A study of Mus musculus with 32 samples.

How the data were processed

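The samples, per the labels, were 32 Illumina MouseRef-8 v2 arrays of cortex and striatum from male wild-type mice after sham surgery or after 2 h of middle cerebral artery occlusion and 2, 8 or 24 h of reperfusion, 4 arrays in each of 8 groups. RNA was extracted with miRNeasy kits and labelled with biotin by MessageAmp, per the labels. The deposited raw table holds the intensity, or signal, of each probe averaged over its beads, without normalization. It names no tool, but its striatal columns equal the signals of the deposited striatal scanner export, which was written by BeadStudio 3.3.7 per the file headers. The detection score in the deposited scanner exports is a fraction, 1 minus the detection p-value, per probe in the striatum and per gene in the cortex. The deposited series table holds a ratio, the value of each array over the mean of the 4 sham arrays of its tissue, as seen from the values, since the sham mean deviated from 1 by at most 1.65e-07. The authors do not state the normalization that preceded this ratio.

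The raw table gave values for 25697 probes, and 837 lines without values were left out. Its 32 columns were taken as labelled. Each column holds the signals of an array that the labels name under another replicate number of the same group, so groups were not affected, and replicate numbers served only in alternatives. The scanner exports hold 1 per-sample column of an array that no label names, which was not used here. For the cortex, where scores were per gene, the detection p of each probe was read from the curve of score against signal of the 13208 genes with 1 probe, array by array. Checked on the striatum, where scores per probe exist, this gave the same call at a detection p of 0.01 for at least 99.944% of probes. Probes were named from a RefSeq table of mouse genes by accession for 23876, by symbol for 728 and by synonym for 709 probes, and 384 kept the name in the file, which gave 17877 gene names. No genome sequence was used here.

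Between 41.5% and 48.2% of probes were detected per array, and median raw signals lay between 57.2 and 103.7. Signals of each tissue were background corrected with a normal-exponential model, offset by 16, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Cortex and striatum were normalized apart for comparisons within a tissue and together for comparisons between tissues. Probes with a detection p under 0.01 in at least 4 of the arrays were tested, 12037 in the cortex, 12482 in the striatum and 12939 over both. Group means were fitted with lmFit and compared with moderated t tests of eBayes, with 12 residual degrees of freedom within a tissue and 24 over both. P-values were adjusted over all tested probes by the Benjamini-Hochberg method, and probes with adjusted p under 0.05 were called. Figures were drawn with matplotlib 3.10.9 in python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

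The 14 comparisons were each reperfusion time against sham in each tissue, 8 h against 2 h and 24 h against 8 h in each tissue, the difference between the striatal and the cortical response at each time, and sham striatum against sham cortex. Named genes were those with the largest changes among genes with a name, taking the brightest probe of each, with adjusted p under 0.05, groups that did not overlap and detection on all 4 arrays of the brighter group. The rule took 8 rises and 8 falls per comparison with sham and 5 and 5 in the others, and named up to 2 rises and 2 falls of each gene list in the comparisons with sham. Further members of the lists, and genes outside this rule, were chosen after their values were seen. A few genes that the rule picked are not reported here. A gene whose dimmer group was undetected on all its arrays has a lower bound in place of a fold, with each dim array set to the higher of its own value and its dimmest detected probe.

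There were 34 gene lists, 17 of pathways and 17 of cell types, with the brightest tested probe of each gene. Pathway lists held immediate early genes, heat shock proteins, the unfolded protein response, hypoxia and glycolysis, cytokines and chemokines, nuclear factor kappa B, interferon, endothelial activation and coagulation, STAT3 and acute phase, antioxidant genes, apoptosis, matrix remodelling, neurotransmitter receptors with channels and synaptic proteins, cell cycle, cholesterol synthesis, circadian clock and glucocorticoid response. Cell type lists held neurons, cortical excitatory neurons, striatal medium spiny neurons, interneurons, astrocytes, reactive astrocytes, oligodendrocytes, their precursors, microglia, neutrophils, monocytes and macrophages, endothelial cells, pericytes, lymphocytes, erythrocytes, choroid plexus and meninges. Some genes are in more than 1 list, among them Timp1, Cd44, Lcn2, Serpina3n, Osmr, Ptx3, Gfap and Cd14. The tissue itself expresses most cell type markers. The test fry asked whether the genes of a list moved on balance in one direction, and its mixed form whether they moved in either. The test camera compared a list with the other probes, with its preset correlation between genes and with a correlation estimated from the data. Each was adjusted over all lists and comparisons of a tissue, or of both tissues together.

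The alternatives were the authors' ratios, no background correction, scaling to the 75th percentile, a detection p under 0.05, no filter on dim probes, BeadChip as a fixed or a random block, replicate number as a block, array weights, all 32 arrays processed together, and leaving out each array in turn. Replicate number by array codes as a block was added after the columns were examined. Chance was assessed with the 35 splits of 8 arrays into 4 and 4, and 100 draws for the tissue responses. Only the procedure after filtering was tested, on simulated data with 200 changed probes. At 24 h against sham it recovered 41.8%, 94.0% and 97.0% of the probes changed by 0.5, 1 and 2 log2 units in the cortex and 34.3%, 88.1% and 97.0% in the striatum, with 4 and 11 false calls. For the difference between tissues it recovered 11.9%, 74.6% and 98.5%, with 4 false calls, and limma made 0 calls on unchanged data. Such rates need not hold where SDs differ. Genes with probes called in opposite directions, such as Eef1d, Esd and H13 in the cortex at 24 h, are not named in the comparisons.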

Results

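Gene expression was measured on 32 Illumina MouseRef-8 v2 bead arrays. RNA came from the right cortex and right striatum, the infarct area, of male wild-type C57BL/6J mice aged 8 to 10 weeks. Middle cerebral artery occlusion, in which a suture in the vessel stops flow, lasted 2 h. Reperfusion then lasted 2, 8 or 24 h. Sham animals received anesthetic and neck incision only. Each of the 8 groups, sham and 3 reperfusion times in each tissue, held 4 arrays. The labels do not state when sham tissue was taken, if each replicate had its own mouse or if tissues share mice. Changes from sham can thus partly reflect sampling time. P-values refer to the spread between these samples, and few arrays limit precision.

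Sham arrays sat at positions A and E of their BeadChips, the slides that carry the arrays, and the 2 h, 8 h and 24 h arrays at positions F, G and H, so position on the slide and group cannot be told apart. Each tissue used 4 BeadChips, and each BeadChip held 1 array of every reperfusion time. Changes are log2 differences between group means ± standard error, with limma p-values adjusted over all tested probes and n = 4 arrays per group. The error is pooled over the fitted groups. It and p can be too small where SDs differ, as for cortex Serpina3n (1.38 at 24 h, 0.20 in sham). Where no array of the dimmer group detected a gene, its fold change is the lower bound defined above. Where 1 to 3 of its arrays did, the change is the fitted one, and its size is approximate because part of that group lay at background. The 34 gene lists and the rule that picked the named genes were fixed before the data were examined.

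The first comparison asked what differed from sham in the cortex after 2 h of reperfusion. The named genes that were higher held chemokines and immediate early genes. The chemokine Ccl4, which attracts leukocytes, was at least 19.8-fold higher (adjusted p = 0.026). Its relative Ccl3 was at least 7.75-fold higher (adjusted p = 0.049), and Timp1, an inhibitor of matrix metalloproteinases, at least 5.76-fold higher (adjusted p = 0.038). Npas4, a transcription factor induced by neuronal activity, rose by 3.25 ± 0.68 log2 units or 9.48-fold (adjusted p = 0.038), and the AP-1 subunit Fosb rose by 2.66 ± 0.37 (adjusted p = 0.0076). The gap junction gene Gjb2, Tmcc3 and the costimulatory receptor gene Cd86 rose by 2.21 ± 0.44, 1.41 ± 0.22 and 1.30 ± 0.27. Some genes of blood vessels were lower. Cldn5, the tight junction protein of the blood-brain barrier, fell by 1.04 ± 0.17 (adjusted p = 0.013). The vascular endothelial growth factor receptor Flt1 fell by 0.87 ± 0.14 (adjusted p = 0.012), and the angiopoietin receptor Tek fell by 0.77 ± 0.15 (adjusted p = 0.031). The chemokine Cxcl12 fell by 0.99 ± 0.16, Fam180a by 1.56 ± 0.23, Narf by 0.83 ± 0.14 and Bahcc1 by 0.74 ± 0.14, and the protocadherin gene Pcdha10 was at least 1.5-fold lower. Without 2 h replicate 1 Npas4 rose by 2.61 and no longer passed, and without 2 h replicate 2 it rose by 3.95 and Ccl4 was at least 30.2-fold higher.

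Of the 24 measured immediate early genes, 3 rose, namely Npas4, Fosb and the phosphatase gene Dusp6 at 0.68 ± 0.15, and 21 did not pass. Adjusted over the list alone 18 rose, and the list had a median of 0.91, 0.84 with undetected members at their bound, and a mean of 1.20 (fry adjusted p = 0.032). Against the other probes camera gave adjusted p = 6.0e-15, and 0.37 with an estimated correlation. Of the 10 endothelial cell markers, 4 fell, with Vwf at -0.68 ± 0.14 beside Cldn5, Flt1 and Tek, and 5 fell adjusted over the list alone (median -0.63, fry adjusted p = 0.0043). By camera the list had adjusted p = 2.0e-06, and 0.22 with estimated correlation. Of the 18 cytokines and chemokines 2 rose and Cxcl12 fell, with fry adjusted p = 0.44. None of the 11 STAT3 and acute phase genes passed, while 4 passed adjusted over the list. The interferon list had a median of -0.51, or -0.37 with undetected at bound, and none of its 14 genes passed (camera adjusted p = 0.0090, and 0.67 with estimated correlation). The astrocyte list moved up on balance with no member past the test (median 0.20, fry adjusted p = 0.025, camera 0.00087, and 0.37 with estimated correlation). Medians and means of the cell cycle, oligodendrocyte precursor and pericyte lists differed in sign, the last at 0.15 and -0.01.

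In all 94 of 12037 probes passed, 48 higher and 46 lower, and 16 and 3 of them changed at least 2-fold. Given a fixed block for BeadChip the count was 114, and all 94 called probes kept their direction within each of the 3 BeadChips that held both groups. There the immediate early list differed by 0.30 to 2.04 and the endothelial list by -0.88 to -0.43. Array weights gave 1184 probes and a random BeadChip block 180. Without sham replicates 1 to 4 in turn 17, 11, 16 and 86 probes passed, and without 2 h replicates 1 to 4 19, 98, 36 and 29 passed. In the same order 9, 11, 12 and 5 and then 10, 0, 7 and 9 of the 16 named genes no longer passed, while Cxcl12, Fam180a, Fosb and Tmcc3 passed without each array. The number of immediate early genes called was then 1, 1, 1, 1, 1, 9, 3 and 1, and that of endothelial markers 4, 1, 0, 2, 2, 3, 2 and 2.

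**Figure D1:**
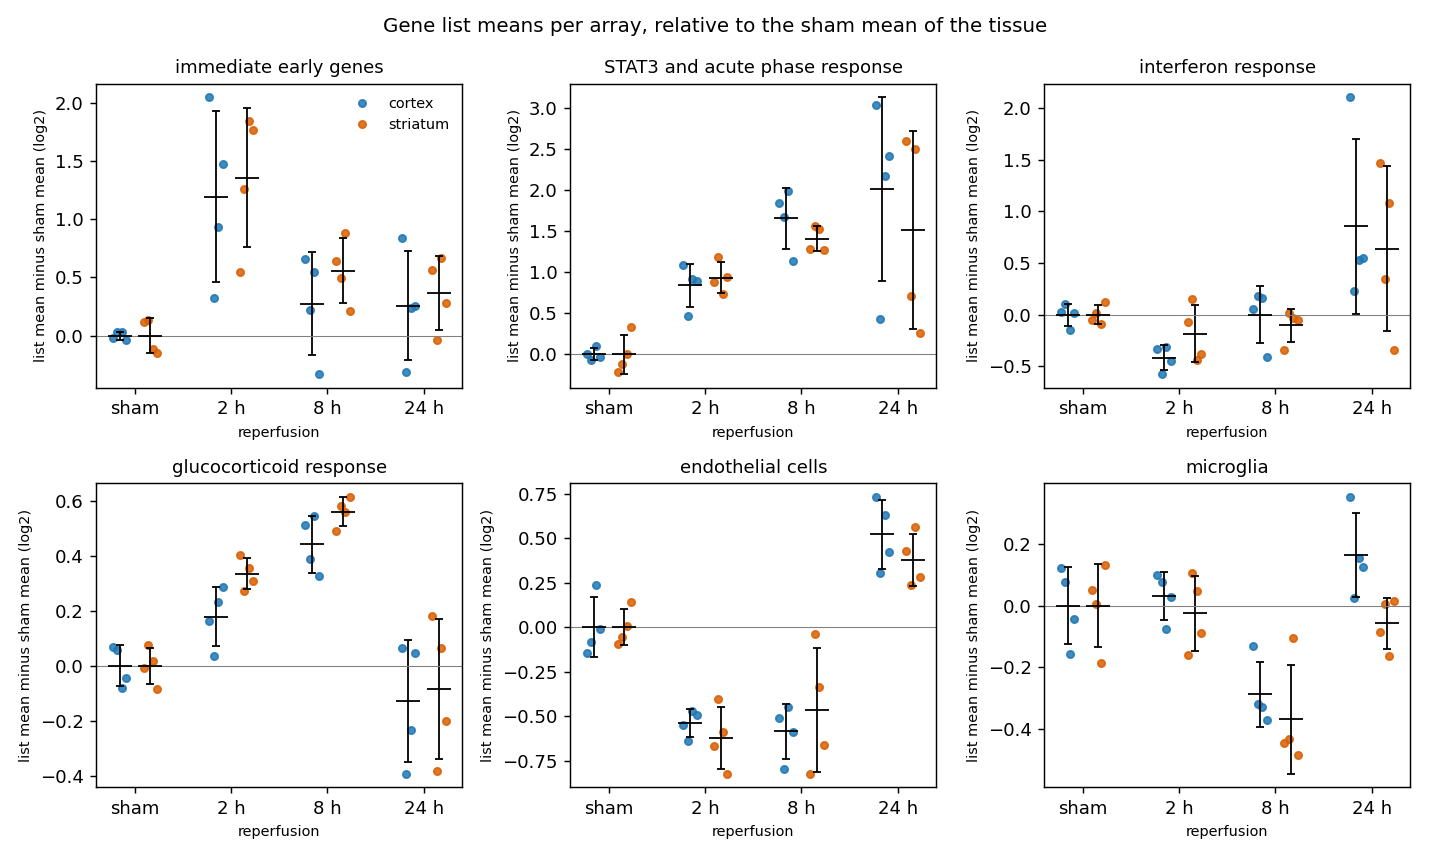
Mean log2 signal of 6 gene lists on each of the 32 arrays, minus the sham mean of the tissue, by group, with black bars for the group mean ± SD of 4 arrays. The acute phase list of the cortex spreads with an SD of 1.12 at 24 h and 0.07 in sham.

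After 8 h of reperfusion the named genes higher in the cortex than in sham held acute phase and chemokine genes. Lcn2, a secreted iron-scavenging acute phase protein, rose by 3.94 ± 0.51 or 15.3-fold (adjusted p = 0.00098). Ccl4 was at least 19.8-fold higher (adjusted p = 0.0093), Timp1 at least 12-fold (adjusted p = 0.0031), and the neutrophil attractant Cxcl1 at least 6.38-fold (adjusted p = 0.024). Hba-a1, the alpha globin of red blood cells, was at least 19.7-fold higher (adjusted p = 0.012). The chemokine Ccl9 rose by 3.38 ± 0.79, the endotoxin co-receptor Cd14 by 3.06 ± 0.80 and the galectin gene Lgals3 by 2.94 ± 0.66. Some vessel genes were lower too. Flt1 fell by 1.45 ± 0.14, which was 2.74-fold lower (adjusted p = 8.2e-05), the endothelial phosphatase gene Ptprb fell by 1.18 ± 0.16 (adjusted p = 0.0013), and the amino acid transporter gene Slc38a5 was at least 1.79-fold lower (adjusted p = 0.0027). The organic cation exporter gene Slc47a1 fell by 1.38 ± 0.23, the calcium pump gene Atp2a3 by 1.20 ± 0.18, Itm2a by 1.14 ± 0.19 and Fam180a by 1.12 ± 0.23. Gpr34, a microglial receptor, fell by 1.35 ± 0.25 (adjusted p = 0.0077). The erythrocyte list stood apart on 8 h replicate 2, at 9.50 against 7.72 on the other 3, and without that array Hba-a1 was at least 12.4-fold higher. Ccl4 was at least 12.8-fold higher without replicate 1 and at least 43.6-fold without replicate 4. Without replicate 4 Cxcl1 was at least 9.64-fold higher, and Ccl9 and Cd14 rose by 4.04 and 3.67.

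Of the 11 STAT3 and acute phase genes 6 rose and 10 rose adjusted over the list (median 1.15, or 1.03 with undetected at bound, fry adjusted p = 0.022). For this list camera gave adjusted p = 4.5e-09, and 0.43 with estimated correlation. The 6 were Lcn2, Cd14, the cytokine signalling inhibitor Socs3 at 2.47 ± 0.62, Serpina3n at 2.02 ± 0.44, the oncostatin receptor gene Osmr at 1.79 ± 0.33 and Cp at 1.03 ± 0.14. Of 13 reactive astrocyte markers 5 rose and 8 rose adjusted over the list (median 1.13, fry adjusted p = 0.056), and 4 of these are also in the acute phase or matrix lists. Of 11 astrocyte markers 4 rose (fry adjusted p = 0.0038, camera 5.5e-05, and 0.29 with estimated correlation), with the intermediate filament gene Gfap at 1.08 ± 0.29 and Gjb6 at 0.52 ± 0.09. Cytokines gave 3 rises and 1 fall, Cxcl12 at -1.11 ± 0.16, among 18 genes. The glucocorticoid-responsive genes Plin4, Fkbp5 and Sult1a1 rose by 2.31 ± 0.32, 1.28 ± 0.15 and 0.85 ± 0.18, 3 of 12 in that list (fry adjusted p = 0.012). By camera the list had adjusted p = 0.0026, and 0.37 with estimated correlation.

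Microglial markers fell in 5 of 15 genes, Gpr34, Siglech at -0.95 ± 0.19, the fractalkine receptor Cx3cr1 at -0.71 ± 0.10, Olfml3 at -0.67 ± 0.16 and Aif1 at -0.64 ± 0.18. Adjusted over the list alone 6 fell and 1 rose. Endothelial markers fell in 4 of 10 genes, and 5 adjusted over the list (fry adjusted p = 0.0038, camera 3.4e-05, and 0.29 with estimated correlation), with Tek at -1.03 ± 0.15, Cldn5 at -0.74 ± 0.17 and Vwf at -0.62 ± 0.14 beside Flt1. The oligodendrocyte gene Ugt8a fell by 0.76 ± 0.16, and the pericyte marker Rgs5 fell by 0.76 ± 0.14. The metallothionein gene Mt2 rose by 1.51 ± 0.31, the cell cycle inhibitor Cdkn1a by 1.48 ± 0.38 and the monocyte marker Ms4a6d by 2.38 ± 0.51. None of the 24 immediate early genes passed. Medians and means differed in sign in the interferon, cholesterol, cortical excitatory neuron, oligodendrocyte, oligodendrocyte precursor and choroid plexus lists.

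The count was 667 of 12037 probes, 354 higher and 313 lower, of which 60 and 18 reached 2-fold. Under a fixed BeadChip block it was 719, and 655 of 667 kept direction in each of 3 BeadChips. Inside single BeadChips the acute phase list differed by 1.17 to 1.88, the endothelial list by -1.04 to -0.39 and the microglial list by -0.33 to -0.16. With array weights 2095 passed and with the authors' values 424. Leaving out sham replicates 1 to 4 in turn gave 222, 170, 328 and 570 probes, and leaving out 8 h replicates 1 to 4 gave 297, 301, 192 and 957. Among the 16 named genes 4, 5, 3 and 1 and then 4, 2, 4 and 0 calls were lost in that order, and Ccl9, Cd14, Cxcl1, Lgals3 and Fam180a were the genes lost at least once. In the same order the acute phase list had 4, 4, 4, 5, 4, 4, 3 and 7 calls, the reactive astrocyte list 4, 4, 4, 4, 4, 4, 3 and 5, the microglial list 3, 3, 4, 3, 5, 3, 3 and 4, the endothelial list 3, 2, 3, 4, 4, 2, 4 and 4, the astrocyte list 2, 1, 1, 3, 1, 2, 1 and 4, the cytokine list 2, 2, 3, 4, 2, 3, 2 and 8 and the glucocorticoid list 3, 2, 3, 3, 3, 3, 3 and 3.

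At 24 h of reperfusion the named genes higher in the cortex than in sham held acute phase and chemokine genes. Lcn2 rose by 4.14 ± 0.51 or 17.6-fold (adjusted p = 0.00073), the acute phase protease inhibitor Serpina3n by 2.95 ± 0.44 (adjusted p = 0.0017), Lgals3 by 4.04 ± 0.66 (adjusted p = 0.0024), the monocyte attractant Ccl12 by 3.82 ± 0.58 (adjusted p = 0.0019) and the osteopontin gene Spp1 by 3.05 ± 0.61 (adjusted p = 0.0074). Timp1 was at least 18.0-fold, Hba-a1 at least 20.8-fold and Ccl4 at least 11.3-fold higher. The largest falls among the named genes held genes of striatal projection neurons. The G protein regulator Rgs9 fell by 1.39 ± 0.36 (adjusted p = 0.022), the phosphodiesterase gene Pde10a by 1.31 ± 0.28 (adjusted p = 0.0088) and the dopamine receptor gene Drd2 by 1.29 ± 0.33 (adjusted p = 0.019). The sodium channel subunit Scn4b fell by 1.32 ± 0.34, Syndig1l by 1.49 ± 0.35, Tmem114 by 1.32 ± 0.17 and Fam180a by 1.14 ± 0.23, and the histone gene H2bc6 fell by 1.34 ± 0.10 (adjusted p = 6.6e-06). Without 24 h replicate 2 the rises were 4.87 for Lcn2, 3.61 for Serpina3n, 4.92 for Lgals3, 4.66 for Ccl12 and 3.93 for Spp1, and at least 31.0-fold, 32.7-fold and 21.9-fold for Timp1, Hba-a1 and Ccl4. Without replicate 1 Lgals3 rose by 3.40 and Spp1 by 2.39, and without replicate 4 Hba-a1 was at least 9.84-fold higher.

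Reactive astrocyte markers rose in 12 of 13 genes, and in 13 adjusted over the list (median 2.22, or 1.67 with undetected at bound, fry adjusted p = 0.0077). The camera test gave adjusted p = 2.2e-12, and 0.37 with estimated correlation. Among them the intermediate filament genes Vim and Gfap rose by 2.22 ± 0.38 and 1.46 ± 0.29 and Emp1 by 2.50 ± 0.65, and 3 of the 4 arrays at 24 h and no sham array detected Nes, which was at least 1.66-fold higher. The STAT3 and acute phase list rose in 9 of 11 genes, with Socs3 at 2.87 ± 0.62 and the amyloid gene Saa3 at least 2.52-fold higher (fry adjusted p = 0.0077). By camera the list had adjusted p = 4.8e-10, and 0.37 with estimated correlation. Matrix remodelling genes rose in 10 of 16, with Mmp14 at 0.80 ± 0.15 and the basement membrane collagens Col4a1 and Col4a2 at 0.90 ± 0.28 and 0.81 ± 0.23 (fry adjusted p = 0.025). For this list camera gave adjusted p = 6.7e-07, and 0.47 with estimated correlation. Cytokines rose in 9 of 18 genes and 1 fell, Cxcl12 at -0.59 ± 0.16 (fry adjusted p = 0.072). The monocyte and macrophage list rose in 4 of 5 genes, with the phagocyte genes Lyz2 and Cd68 at 1.66 ± 0.23 and 1.89 ± 0.32 (fry adjusted p = 0.0077, camera 0.00024, and 0.37 with estimated correlation). The neutrophil genes S100a8 and S100a9, 2 of 4 measured, were detected on 3 of 4 arrays at 24 h and on no sham array, and were at least 12.2-fold and 5.77-fold higher. Of the 24 h arrays replicate 2 lay nearest to sham, with list means of 6.58 against 9.70, 8.71 and 8.99 on replicates 1, 3 and 4 for reactive astrocytes, 7.18 against 9.80, 8.92 and 9.17 for the acute phase and 5.76 against 8.67, 7.48 and 10.2 for neutrophils, where the highest sham arrays were at 6.28, 6.85 and 5.79. Without it Emp1 and Socs3 rose by 3.34 and 3.66, and Nes, S100a8 and S100a9 were at least 2.55-fold, 29.3-fold and 13.1-fold higher. Without replicate 4 S100a8 was at least 5.70-fold higher, and S100a9, at least 2.71-fold, no longer passed.

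Endothelial markers, lower at 2 and 8 h, rose in 5 of 10 genes and in 6 adjusted over the list (fry adjusted p = 0.0058). The camera test gave adjusted p = 0.0013, and 0.37 with estimated correlation. Vwf rose by 1.37 ± 0.14 (adjusted p = 0.00016), the adhesion gene Pecam1 by 1.03 ± 0.29 and Cldn5 by 0.91 ± 0.17. Endothelial activation genes rose in 6 of 12, with Lrg1 at 1.78 ± 0.28 and the angiopoietin gene Angpt2 at 1.62 ± 0.38 (fry adjusted p = 0.022, camera 3.1e-05, and 0.43 with estimated correlation). Complement genes of the microglial list rose, C1qb by 0.92 ± 0.18 and C1qc by 0.85 ± 0.15, with 4 of 15 markers higher and Siglech lower at -0.94 ± 0.19. Neurotransmitter receptor, channel and synaptic genes fell in 7 of 23, and in 10 adjusted over the list (median -0.36, or -0.32 with undetected at bound, fry adjusted p = 0.025). By camera the list had adjusted p = 6.6e-06, and 0.52 with estimated correlation. The extrasynaptic GABA receptor subunit Gabrd fell by 0.78 ± 0.20, the potassium channel subunit Kcnj4 by 0.69 ± 0.16 and the glutamate receptor subunit Gria3 by 0.69 ± 0.18. Medium spiny neuron markers fell in 3 of 9 genes and in 6 adjusted over the list (median -0.95, fry adjusted p = 0.072). The dendritic gene Map2 fell by 0.44 ± 0.10, 1 of 11 neuron markers, and none of the 8 cortical excitatory neuron markers passed (mean -0.04).

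The other lists gave fewer calls. The interferon list had 3 rises among 14 genes, led by Ifitm3 at 1.72 ± 0.31, the antioxidant list 4 among 17 with Gpx1 at 0.66 ± 0.15 and Nqo1 at 0.64 ± 0.13, the hypoxia list 2 among 17 with hexokinase Hk2 at 1.11 ± 0.21, and the nuclear factor kappa B list 2 rises and 1 fall among 10 with Irf1 at 0.88 ± 0.23. The unfolded protein list had 2 rises and 2 falls among 21, with the cystine transporter Slc7a11 at 0.99 ± 0.20 and Ddit4 at -0.53 ± 0.09, and the apoptosis list 1 and 1 among 20. Falls numbered 2 of 24 immediate early genes, 1 of 19 heat shock genes, 1 of 8 cell cycle genes, 2 of 12 glucocorticoid genes with Tsc22d3 at -0.49 ± 0.11, and 1 of 3 pericyte markers, Rgs5 at -0.75 ± 0.14. Rises numbered 1 of 11 astrocyte markers, 1 of 5 oligodendrocyte precursor markers, 2 of 6 meningeal markers with Mgp at 0.91 ± 0.17, and 1 of 2 erythrocyte genes. The oligodendrocyte list had 2 rises and 1 fall among 11, Mobp at 0.63 ± 0.19 and Ugt8a at -0.92 ± 0.16. No gene passed among 14 cholesterol synthesis, 14 circadian clock, 8 interneuron, 9 choroid plexus and 1 lymphocyte genes. Median and mean differed in sign in the heat shock, hypoxia and oligodendrocyte precursor lists, where fry and camera also differed for the last. The interferon list stood apart on 24 h replicate 1, at 9.01 against 7.35 on the other 3.

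In total 1520 of 12037 probes passed, 755 higher and 765 lower, and 191 of the higher and 20 of the lower changed at least 2-fold. With BeadChip as a fixed block 2130 passed, and 1408 of 1520 kept direction in each of 3 BeadChips. On single BeadChips the acute phase list differed by 0.33 to 3.08, the neutrophil list by -0.03 to 4.55, the endothelial list by 0.07 to 0.84 and the medium spiny neuron list by -1.28 to -0.38. The count was 821, 836, 893 and 1058 without sham replicates 1 to 4 in turn and 708, 2762, 1179 and 770 without 24 h replicates 1 to 4. Drd2, Rgs9 and Scn4b no longer passed without sham replicate 3 or 24 h replicate 1, Rgs9 without sham replicate 4 or 24 h replicate 3, and Scn4b without 24 h replicate 4, while the other 13 named genes passed without each array. In the same order the calls numbered 8, 9, 10, 10, 7, 13, 9 and 7 for reactive astrocytes, 7, 7, 7, 7, 7, 11, 7 and 7 for the acute phase, 4, 5, 5, 8, 3, 12, 7 and 3 for matrix, 5, 4, 4, 6, 3, 16, 9 and 5 for cytokines, 4, 6, 5, 5, 1, 12, 5 and 3 for neurotransmitter, 2, 2, 4, 2, 2, 7, 2 and 3 for endothelial, 5, 5, 3, 5, 3, 8, 6 and 4 for endothelial activation, 5, 4, 3, 5, 3, 11, 5 and 4 for microglial and 3, 4, 1, 2, 1, 6, 2 and 4 for medium spiny neuron genes.

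In the striatum at 2 h of reperfusion, some immediate early genes and the chemokine Ccl4 were higher than in sham. Ccl4 was at least 17.4-fold higher (adjusted p = 0.028) and Npas4 at least 5.46-fold (adjusted p = 0.019). Timp1, which 1 of 4 sham arrays detected, rose by 3.40 ± 0.57 (adjusted p = 0.024), Fosb by 2.54 ± 0.44 and Junb, another AP-1 subunit, by 2.06 ± 0.36 (adjusted p = 0.024 for each). Gjb2 rose by 2.07 ± 0.31 (adjusted p = 0.019), Sertad1 by 1.44 ± 0.24 and the cyclic AMP phosphodiesterase Pde4d by 1.21 ± 0.21. The brain endothelial transporter Slco1a4 fell by 1.23 ± 0.18 (adjusted p = 0.019), Cxcl12 by 0.98 ± 0.15, Zfp157 by 0.78 ± 0.14, the amino acid transporter Slc38a2 by 0.69 ± 0.12 and Kank3 by 0.68 ± 0.13. Of the 23 immediate early genes 3 rose and 19 rose adjusted over the list (median 1.15, or 1.10 with undetected at bound, fry adjusted p = 0.014). For this list camera gave adjusted p = 3.6e-25, and 0.31 with estimated correlation. Of the 10 endothelial markers 1 fell and 6 fell adjusted over the list (median -0.61, fry adjusted p = 0.035). The camera test gave adjusted p = 9.0e-08, and 0.40 with estimated correlation. Among cytokines 1 rose and 1 fell of 17, and 7 rose adjusted over the list. Cholesterol synthesis genes had a median of 0.36 with 5 of 14 higher adjusted over the list and none over all probes (camera adjusted p = 2.2e-06, and 0.54 with estimated correlation). Medians and means of the neuron, microglial and pericyte lists differed from each other or from a test in sign, all within 0.08 of 0. Without 2 h replicate 1 Fosb rose by 3.15.

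Few probes passed, 20 of 12482, 13 higher and 7 lower, with 11 and 1 of at least 2-fold. A fixed block for BeadChip gave 13, 10 higher and 3 lower, and all 20 kept direction in each of 3 BeadChips. Within BeadChips the immediate early list differed by 0.42 to 1.99. The authors' deposited values gave 8 probes, and fry then called no list. All 32 arrays processed together gave 31 higher and 34 lower. Array weights gave 94 and no filter on dim probes 1. Single arrays moved the count, since 1, 0, 0 and 3 probes passed without sham replicates 1 to 4 in turn and 31, 3, 6 and 0 without 2 h replicates 1 to 4. In that order 12, 13, 13 and 11 and then 3, 10, 7 and 13 of the 13 named genes were lost, so none passed in all of these omissions, and 0, 0, 0, 0, 9, 1, 1 and 0 immediate early genes and 1, 0, 0, 0, 1, 1, 1 and 0 endothelial markers were called.

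In the striatum at 8 h of reperfusion the named genes higher than in sham held chemokine and acute phase genes. Timp1, detected on 1 of 4 sham arrays, rose by 4.08 ± 0.57 (adjusted p = 0.0021), Socs3, detected on 2, by 2.92 ± 0.67 (adjusted p = 0.025), Lcn2 by 2.97 ± 0.81 (adjusted p = 0.049) and Cd14 by 2.86 ± 0.63 (adjusted p = 0.022). Ccl4 was at least 22.4-fold higher (adjusted p = 0.0060), Ccl3 at least 7.65-fold and Cxcl1 at least 7.19-fold, and Hba-a1 rose by 3.73 ± 0.98 (adjusted p = 0.042). Of the genes that fell, Unc80, a part of the sodium leak channel complex, was at least 2.06-fold lower, Gpr34 at least 2.16-fold and the endothelial matrix gene Mmrn2 at least 1.42-fold lower. Fam180a fell by 1.51 ± 0.30, Itm2a by 1.35 ± 0.27, the serotonin receptor Htr1d by 1.21 ± 0.28 and Aif1l by 1.08 ± 0.21, and Slc47a1 was 2.83-fold lower. Hba-a1 and Cxcl1 lost their calls whichever of the 8 arrays was left out, and without 8 h replicate 4 Hba-a1 rose by 3.09.

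Acute phase genes rose in 5 of 12, and in 9 adjusted over the list (median 1.20, or 0.81 with undetected at bound, fry adjusted p = 0.094). By camera the list had adjusted p = 6.9e-07, and 0.63 with estimated correlation. Reactive astrocyte markers rose in 5 of 14, with Serpina3n at 1.97 ± 0.46 and Osmr at 1.66 ± 0.38 (median 1.38, or 0.70 with undetected at bound, fry adjusted p = 0.094). Glucocorticoid-responsive genes rose in 5 of 12, with Plin4 at 2.23 ± 0.35, Fkbp5 at 1.35 ± 0.20 and Sult1a1 at 1.04 ± 0.13 (fry adjusted p = 0.0085). For this list camera gave adjusted p = 1.7e-05, and 0.40 with estimated correlation. Microglial markers fell in 3 of 15, with Cx3cr1 at -0.97 ± 0.15 and Aif1 at -0.92 ± 0.13. The microglial list stood apart on 8 h replicate 3, at 7.94 against 7.59. Endothelial markers fell in 3 of 10 and in 5 adjusted over the list, with Flt1 at -0.93 ± 0.21 and Slco1a4 at -0.83 ± 0.18. Cytokines gave 3 rises and 1 fall among 17. The DNA damage gene Gadd45b rose by 1.66 ± 0.40, the heat shock gene Hspa1a by 2.17 ± 0.59, Mt2 by 1.56 ± 0.37 and Cdkn1a by 1.80 ± 0.40, while the astrocyte water channel Aqp4 fell by 0.77 ± 0.15 and Rgs5 by 0.93 ± 0.18. None of the 9 medium spiny neuron markers passed over all probes, 6 passed as lower adjusted over the list, and their mean was -1.09 (camera adjusted p = 0.00025, and 0.67 with estimated correlation). The cortical excitatory neuron list had the opposite sign in the same block, with none of its 7 genes past the test and a mean of 0.70 (fry adjusted p = 0.26, camera 0.014, and 0.70 with estimated correlation). Within BeadChips the medium spiny neuron list differed by -1.93 to -0.70 and the cortical excitatory neuron list by 0.13 to 1.29.

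Past the threshold were 478 of 12482 probes, 220 higher and 258 lower, of which 61 and 25 reached 2-fold. Given a fixed block for BeadChip there were 680, and 471 of 478 kept direction in each of 3 BeadChips. Inside single BeadChips the acute phase list differed by 1.19 to 1.57 and the glucocorticoid list by 0.46 to 0.64. The authors' deposited values gave 50 higher and 89 lower probes, and fry then called no list. Array weights gave 1041 probes, all 32 arrays processed together 973 and no filter on dim probes 299. Omitting sham replicates 1 to 4 in turn left 125, 138, 124 and 568 probes, and omitting 8 h replicates 1 to 4 left 309, 256, 221 and 228. The 16 named genes lost 9, 9, 10 and 3 and then 6, 5, 8 and 5 calls in that order, with Aif1l, Ccl3, Ccl4, Fam180a, Timp1 and Unc80 passing without each array. The acute phase list then had 0, 0, 0, 5, 2, 1, 0 and 3 calls, the reactive astrocyte list 1, 1, 1, 5, 3, 1, 1 and 3, the glucocorticoid list 3, 3, 3, 4, 5, 4, 4 and 3, the microglial list 2, 2, 2, 3, 3, 3, 2 and 2, the endothelial list 1, 0, 0, 2, 1, 3, 1 and 0 and the cytokine list 3, 3, 3, 3, 3, 3, 3 and 3.

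By 24 h of reperfusion the striatum held more probes that differed from sham than at the earlier times. Timp1, again detected on 1 of 4 sham arrays, rose by 4.23 ± 0.57 (adjusted p = 0.00099), Socs3, detected on 2, by 2.89 ± 0.67 (adjusted p = 0.011), Ccl12 by 2.84 ± 0.65 (adjusted p = 0.0099) and Serpina3n by 2.73 ± 0.46 (adjusted p = 0.0032). The tubulin gene Tubb6 rose by 2.60 ± 0.63, the immunoglobulin receptor Fcgr4 by 2.27 ± 0.50, Gjb2 by 2.19 ± 0.31 and Ms4a6d by 2.18 ± 0.55. Nf1, a negative regulator of Ras, was at least 2.03-fold lower (adjusted p = 0.00081), and Depp1 at least 2.39-fold lower (adjusted p = 0.0031). The brain metallothionein Mt3 fell by 1.45 ± 0.31 (adjusted p = 0.0081), the sulfurtransferase Tst by 1.43 ± 0.19, Plekhf1 by 1.41 ± 0.17, Syndig1l by 1.43 ± 0.41, the clathrin adaptor subunit Ap2a1 by 1.42 ± 0.29 and Cacng4, an auxiliary subunit of AMPA receptors, by 1.28 ± 0.24. Without 24 h replicate 4 the rises were 4.90 for Timp1, 3.67 for Socs3, 3.56 for Ccl12, 3.37 for Tubb6 and 2.85 for Ms4a6d. Without 24 h replicate 1 Socs3 rose by 2.26 and Tubb6 by 2.00.

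Acute phase genes rose in 9 of 12, and in 11 adjusted over the list (median 1.52, or 1.19 with undetected at bound, fry adjusted p = 0.071, camera 2.2e-06, and 0.67 with estimated correlation), with Stat3 at 0.97 ± 0.25 and the complement gene C3 at 1.09 ± 0.31. Reactive astrocyte markers rose in 8 of 14 and in 13 adjusted over the list, with Emp1 at 1.85 ± 0.59 and Osmr at 1.56 ± 0.38. Cytokines rose in 8 of 17, with the macrophage growth factor Csf1 at 1.14 ± 0.25. Matrix genes gave 6 rises and 1 fall among 15 with Mmp14 at 0.74 ± 0.18 and Timp3 at -0.64 ± 0.12. The monocyte and macrophage list rose in 4 of 8, with Cd68 at 1.24 ± 0.23, and endothelial activation genes rose in 5 of 12, with Lrg1 at 1.88 ± 0.47 and Thbd at 1.47 ± 0.35. None of these 5 lists passed fry, with adjusted p = 0.084, 0.094, 0.12, 0.061 and 0.12, and their camera calls were lost, with adjusted p = 0.67, 0.67, 0.67, 0.63 and 0.67 with estimated correlation. The order is reactive astrocytes, cytokines, matrix, monocytes and endothelial activation. Cell cycle genes rose in 2 of 8, with the replication helicase subunit Mcm6 at 1.19 ± 0.20 (fry adjusted p = 0.035, camera 0.014, and 0.63 with estimated correlation). With the authors' values fry did not call that list (adjusted p = 0.28). None of the 9 medium spiny neuron markers passed, with a mean of -0.76. Without 24 h replicate 4 Emp1 rose by 2.48.

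Several lists held members on either side. In the hypoxia list Hk2 rose by 1.41 ± 0.24 and Higd1a by 0.98 ± 0.21 and Ndrg1 fell by 0.61 ± 0.13, 3 rises and 3 falls among 17 (mixed fry adjusted p = 3.1e-06). In the nuclear factor kappa B list Irf1 rose by 1.13 ± 0.21 and Rela by 0.68 ± 0.14, and the inhibitor Nfkbia fell by 0.93 ± 0.19 (mixed fry adjusted p = 8.9e-06). Glucocorticoid genes gave 1 rise, Sult1a1 at 0.71 ± 0.13, and 4 falls, with Sgk1 at -0.77 ± 0.17. The chaperone genes Fkbp4 and Stip1 fell by 0.84 ± 0.10 and 0.43 ± 0.11, 3 of 19 in their list, Ddit4 fell by 1.02 ± 0.13, and oligodendrocyte genes fell in 3 of 11, with Ugt8a at -0.83 ± 0.19. Endothelial Cldn5 rose by 0.89 ± 0.19, 1 of 10 in its list, and 4 of 22 neurotransmitter genes fell, with Syn2 at -0.59 ± 0.16. Median and mean or test differed in sign in the heat shock, hypoxia, nuclear factor kappa B, circadian and astrocyte lists.

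The count reached 2067 of 12482 probes, 1055 higher and 1012 lower, with 134 and 52 of at least 2-fold. Under a fixed BeadChip block it was 2389, and 2024 of 2067 kept direction in each of 3 BeadChips. On single BeadChips the acute phase list differed by 0.71 to 2.77 and the monocyte list by 0.82 to 2.34. The authors' deposited values gave 300 higher and 476 lower probes. Sham replicates 1 to 4 left out in turn gave 951, 1538, 1153 and 1827 probes, and 24 h replicates 1 to 4 gave 1030, 1924, 1256 and 2162. Only Syndig1l and Ms4a6d of the 16 named genes lost their call without some array, with 1, 1, 1 and 0 and then 1, 0, 2 and 0 lost in that order. In the same order the calls numbered 3, 6, 7, 9, 5, 9, 5 and 10 in the acute phase list, 3, 4, 4, 6, 4, 10, 4 and 12 for reactive astrocytes, 4, 4, 4, 6, 3, 12, 3 and 13 for cytokines, 3, 4, 4, 5, 4, 9, 4 and 10 for matrix, 4, 3, 4, 5, 2, 3, 1 and 7 for monocytes, 2, 4, 3, 6, 2, 8, 3 and 7 for endothelial activation and 4, 5, 4, 4, 5, 5, 4 and 4 in the glucocorticoid list.

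**Figure D2:**
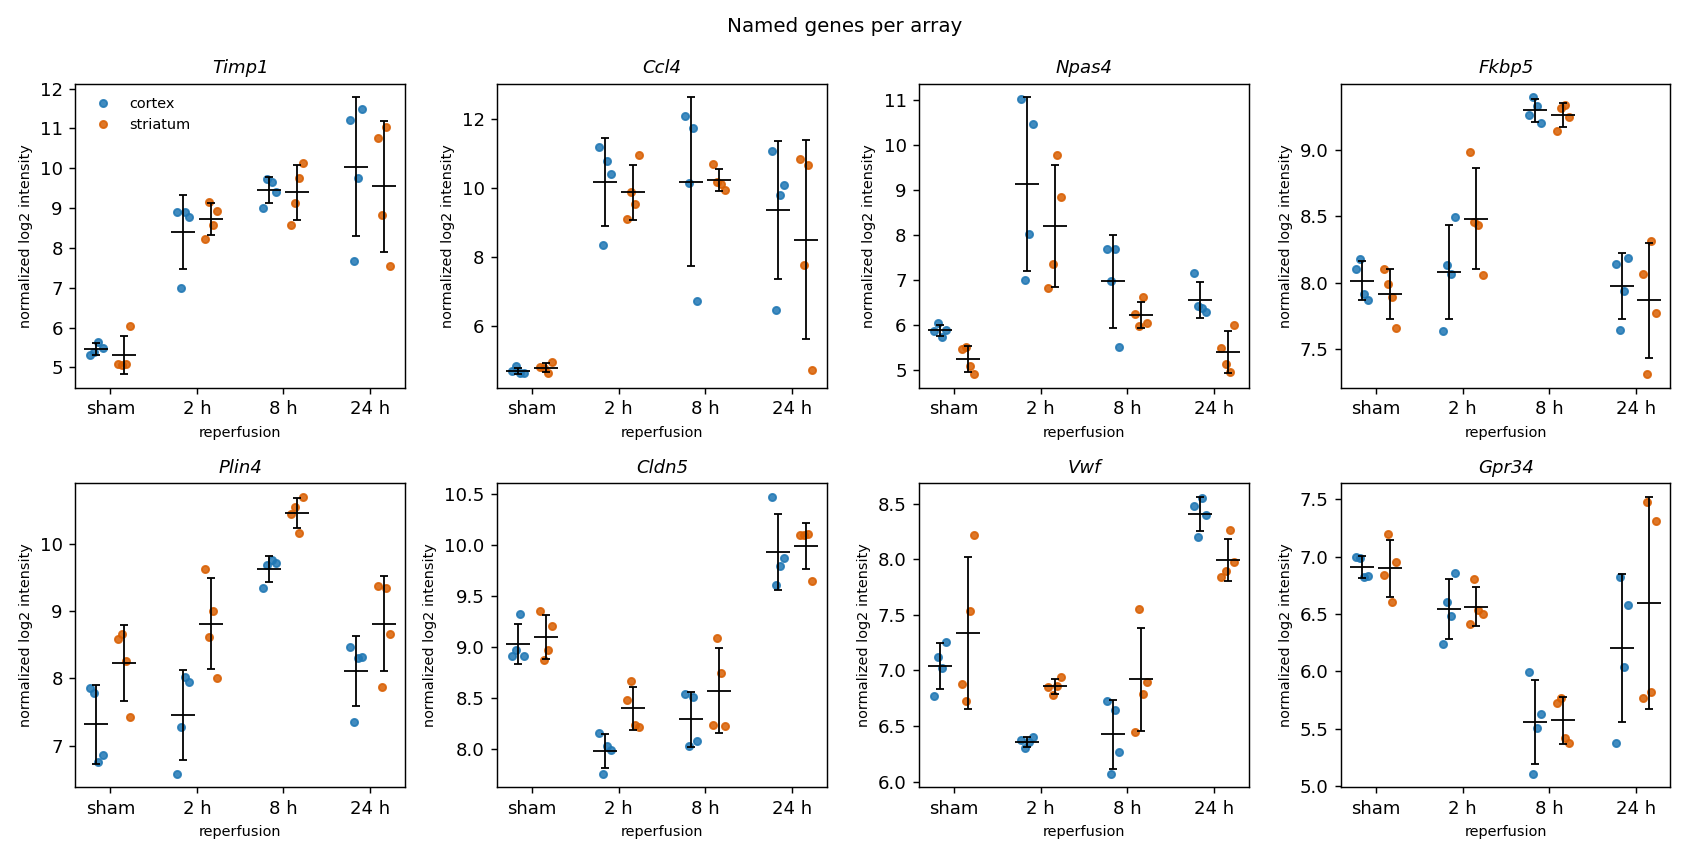
Normalized log2 intensity of 8 named genes on each array at sham, 2 h, 8 h and 24 h of reperfusion, cortex in blue and striatum in orange, with bars for the mean ± SD of 4 arrays. Timp1 rises from sham at every time in both tissues, and Vwf in the cortex ends 1.37 above sham at 24 h.

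Comparing 8 h with 2 h in the cortex, some immediate early genes fell and some glucocorticoid-responsive genes rose, while fry called neither list. Fosb fell by 2.11 ± 0.37 (adjusted p = 0.015), and the zinc finger factors Egr4 and Egr1 fell by 2.00 ± 0.37 and 1.12 ± 0.22 (adjusted p = 0.021 and 0.029). The lipid droplet gene Plin4 rose by 2.17 ± 0.32 (adjusted p = 0.0075), and Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 1.21 ± 0.15 (adjusted p = 0.0018). Ddc, which makes dopamine and serotonin, rose by 1.05 ± 0.19, the chemokine Ccl17 by 1.01 ± 0.18, and the collagen receptor Itga11 was at least 1.71-fold higher, while Slc47a1 fell by 1.20 ± 0.23. Of 24 immediate early genes 5 fell and 10 fell adjusted over the list (median -0.79, or -0.69 with undetected at bound, fry adjusted p = 0.055, camera 6.6e-13, and 0.37 with estimated correlation), and 3 of 12 glucocorticoid genes rose (fry adjusted p = 0.072). The microglial gene Cx3cr1 fell by 0.60 ± 0.10, and 6 of 15 microglial markers fell adjusted over the list (camera adjusted p = 0.00018, and 0.37 with estimated correlation).

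There were 70 of 12037 probes past the threshold, 31 higher and 39 lower at 8 h. With BeadChip as a fixed block there were 88, and all 70 kept direction in each of the 4 BeadChips. Within BeadChips the immediate early list differed by -1.81 to -0.11. The authors' deposited values gave 39 higher and 26 lower, and all 32 arrays processed together 24 and 19. A random BeadChip block gave 121 probes, array weights 449 and no filter on dim probes 45. With each of the 2 h replicates 1 to 4 left out the count was 32, 66, 25 and 28, and with each of the 8 h replicates 71, 24, 25 and 70. The 9 named genes lost 4, 1, 5 and 5 and then 1, 6, 6 and 2 calls, with Fkbp5 and Plin4 passing without each array, and 3, 7, 3, 0, 5, 0, 2 and 3 immediate early genes were called.

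From 8 h to 24 h in the cortex, which used the same 8 h arrays as the step from 2 h, endothelial genes rose. The clotting factor carrier Vwf rose by 1.98 ± 0.14 or 3.95-fold (adjusted p = 1.4e-06), the lysozymes Lyz1 and Lyz2 by 1.89 ± 0.25 and 1.87 ± 0.23 (adjusted p = 0.00061 and 0.00039), and the interferon-induced Oasl2 by 1.70 ± 0.40 (adjusted p = 0.023). Slc38a5 was at least 2.14-fold higher. Plin4 and Fkbp5 fell by 1.51 ± 0.32 and 1.32 ± 0.15 (adjusted p = 0.015 and 0.00035), the Wnt receptor Fzd2 by 1.11 ± 0.23, Alox12b by 1.30 ± 0.26, and Mfsd2a, a lipid transporter of the blood-brain barrier, by 1.09 ± 0.15 (adjusted p = 0.00088). Endothelial markers rose in 8 of 10 genes and in 9 adjusted over the list, with Flt1 at 1.69 ± 0.14 and Cldn5 at 1.65 ± 0.17 (median 1.04, fry adjusted p = 1.1e-05, camera adjusted p = 1.8e-12). With an estimated correlation camera gave adjusted p = 0.043, and no other camera call of any list passed in that form. This call was lost with BeadChip as a fixed block (adjusted p = 0.19), while fry still called the list (adjusted p = 0.0002). Microglial markers rose in 4 of 15, Aif1 by 1.12 ± 0.18 and Cx3cr1 by 1.09 ± 0.10 (fry adjusted p = 0.0038). For this list camera gave adjusted p = 3.9e-06, and 0.29 with estimated correlation. Interferon genes rose in 6 of 14, with Bst2 at 1.29 ± 0.26 (fry adjusted p = 0.082). On 24 h replicate 1 the interferon list stood apart, at 9.01 against 7.35, and so did Oasl2, at 9.27 against 6.97 on the other 3. Without that array Oasl2 rose by 1.13. Glucocorticoid genes fell in 6 of 12 (fry adjusted p = 0.00073, camera 3.0e-06, and 0.22 with estimated correlation), and circadian clock genes in 3 of 14, with Per3 at -0.70 ± 0.15 (fry adjusted p = 0.0038, camera 0.033, and 0.37 with estimated correlation).

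The count was 652 probes, 306 higher and 346 lower at 24 h, and 898 with BeadChip as a fixed block. Within each of the 4 BeadChips 626 of the 652 kept their direction, and the endothelial list differed by 1.01 to 1.24, the microglial list by 0.34 to 0.49 and the interferon list by 0.05 to 2.04. Leaving out the 8 h replicates 1 to 4 in turn gave 391, 310, 314 and 568 probes, and leaving out the 24 h replicates 323, 1489, 426 and 350. Of the 10 named genes only Oasl2 lost its call, without 8 h replicate 2. In the same order 5, 4, 6, 6, 5, 8, 5 and 5 endothelial, 4, 3, 3, 3, 4, 7, 3 and 3 microglial, 3, 2, 4, 5, 5, 8, 5 and 5 interferon and 4, 4, 4, 6, 5, 5, 4 and 5 glucocorticoid genes were called.

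In the striatum from 2 h to 8 h, Plin4 rose by 1.64 ± 0.35 (adjusted p = 0.034), the kinase gene Sgk3 by 1.22 ± 0.18 (adjusted p = 0.0048), the sulfotransferase Sult1a1 by 1.09 ± 0.13 (adjusted p = 0.0021), the nuclear corepressor Hr by 0.77 ± 0.13 and Mbip by 0.78 ± 0.18. Egr4 fell by 2.45 ± 0.54 (adjusted p = 0.036), Npas4 by 1.97 ± 0.45 (adjusted p = 0.046), Crim1 by 1.25 ± 0.17 and the guanine deaminase Gda by 1.22 ± 0.25, and Unc80 was at least 2.31-fold lower. Of 23 immediate early genes 2 fell and 8 fell adjusted over the list (fry adjusted p = 0.10). By camera the list had adjusted p = 7.1e-08, and 0.63 with estimated correlation. The microglial genes Cx3cr1 and Aif1 fell by 0.94 ± 0.15 and 0.66 ± 0.13, the glutamate receptor subunits Gria3 and Gria1 by 0.79 ± 0.18 and 0.74 ± 0.15, and Aqp4 by 0.72 ± 0.15. The count was 140 of 12482 probes, 37 higher and 103 lower, and 183 with BeadChip as a fixed block, and all 140 kept their direction within each of the 4 BeadChips. Inside single BeadChips the immediate early list differed by -1.55 to 0.09. The authors' deposited values gave 9 higher and 10 lower. All 32 arrays processed together gave 348 probes, array weights 295 and no filter on dim probes 86. Without 2 h replicates 1 to 4 in turn 84, 34, 150 and 36 probes passed, and without 8 h replicates 1 to 4 70, 54, 116 and 61. The 10 named genes lost 2, 5, 2 and 5 and then 3, 5, 3 and 5 calls, with Crim1, Hr, Sgk3, Sult1a1 and Unc80 passing without each array, and 4, 0, 0, 0, 1, 0, 1 and 0 immediate early genes were called in the same order.

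From 8 h to 24 h in the striatum, again with the same 8 h arrays, Slc38a5 rose by 2.06 ± 0.38 (adjusted p = 0.0056), Oasl2 by 2.01 ± 0.38 (adjusted p = 0.0060), the endothelial adhesion gene Icam2 by 1.85 ± 0.21 (adjusted p = 0.00026), Lyz1 by 1.83 ± 0.26 and Cldn5 by 1.41 ± 0.19 (adjusted p = 0.00081). Plin4 fell by 1.65 ± 0.35, Fosb by 1.73 ± 0.44 and Mt3 by 1.60 ± 0.31 (adjusted p = 0.0066), and Depp1 and Nf1 were at least 2.58-fold and 1.63-fold lower. Endothelial markers rose in 6 of 10 and in 7 adjusted over the list (median 0.82, fry adjusted p = 0.0057). For this list camera gave adjusted p = 1.6e-06, and 0.40 with estimated correlation. Glucocorticoid genes fell in 7 of 12, with Fkbp5 at -1.39 ± 0.20, Arrdc2 at -0.97 ± 0.12 and Pdk4 at -1.05 ± 0.17 (median -0.89, fry adjusted p = 0.0017). The camera test gave adjusted p = 1.9e-05, and 0.40 with estimated correlation. Interferon genes rose in 4 of 15, with Bst2 at 1.35 ± 0.28, and microglial genes in 4 of 15, with Cx3cr1 at 1.32 ± 0.15 (fry adjusted p = 0.17 and 0.094). Lyz2 rose by 1.38 ± 0.26 and Cd68 by 0.85 ± 0.23, among 4 of 8 in the monocyte list. Hspa1a fell by 2.41 ± 0.59, and 3 of 19 heat shock genes fell.

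Here 1502 of 12482 probes passed, 684 higher and 818 lower at 24 h, and 1606 with BeadChip as a fixed block. Within each of the 4 BeadChips 1437 of the 1502 kept their direction, and the endothelial list differed by 0.28 to 1.25, the glucocorticoid list by -0.96 to -0.31 and the interferon list by -0.29 to 1.81. The authors' deposited values gave 309 probes, and fry then called no list. All 32 arrays processed together gave 2331. Leaving out each 8 h replicate in order gave 2007, 1060, 830 and 487 probes, and each 24 h replicate 669, 884, 1226 and 1325. Fosb alone among the 10 named genes lost its call, without 8 h replicate 3 or 24 h replicates 1 or 2, and 5, 6, 5, 4, 5, 6, 5 and 6 endothelial, 9, 7, 8, 7, 7, 7, 7 and 7 glucocorticoid and 3, 3, 3, 2, 2, 3, 2 and 11 interferon genes were called.

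Whether the striatum and the cortex responded differently was tested as the difference between their changes from sham. At 2 h limma called 0 of 12939 probes, with 679 at an unadjusted p under 0.05. At 8 h it called 2. Hr changed by 1.23 ± 0.20 more in the striatum (adjusted p = 0.011), and the purine synthesis gene Gart by -0.72 ± 0.13 (adjusted p = 0.041). Hr lost its call without cortex sham replicate 2 or striatum sham replicate 4. Gart passed only without cortex 8 h replicate 1, striatum sham replicate 1 or striatum 8 h replicate 4. At 24 h 110 probes passed, 40 with a higher and 70 with a lower change in the striatum. Gda differed by 1.46 ± 0.31 (adjusted p = 0.025), the deubiquitinase Otub2 by 1.27 ± 0.24 (adjusted p = 0.017), Sec14l2 by 1.25 ± 0.23, Tmem114 by 1.25 ± 0.31 and the chromatin remodelling subunit Smarcc1 by 1.23 ± 0.23. On the other side were Mt3 at -1.61 ± 0.36 (adjusted p = 0.026), Nf1 at -1.35 ± 0.29, the heat shock factor Hsf4 at -1.22 ± 0.30, Josd2 at -1.16 ± 0.22 and Tst at -1.07 ± 0.22. The complement genes C1qb and C1qc, which belong to the 15 microglial markers, changed by -1.01 ± 0.25 and -0.98 ± 0.21 in the striatum relative to the cortex, and the chaperone Fkbp4 by -0.66 ± 0.14. No other list held a called gene at any time.

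By camera the cholesterol synthesis and cortical excitatory neuron lists were higher in the striatal response at 8 h, with means of 0.35 and 0.59 (adjusted p = 0.0019 and 0.0024), and the oligodendrocyte list was lower at 24 h, with a mean of -0.40 (adjusted p = 0.011). All 3 had adjusted p = 1 with estimated correlation, and fry called no list. Given a fixed block for BeadChip the counts at 2, 8 and 24 h were 0, 1 and 129. The authors' values gave 0, 1 and 0 by limma, with 388, 440 and 1662 probes at an unadjusted p under 0.05, so the calls at 24 h depended on the values used. Scaling to the 75th percentile gave 84 higher and 52 lower probes at 24 h. At 24 h array weights gave 756, a random BeadChip block 258, no background correction 196 and filtering at a detection p under 0.05 gave 70, and at 8 h this detection limit and the scaling gave 1 each. At 8 h the count without cortex sham replicates 1 to 4 was 1, 0, 1 and 1, without cortex 8 h replicates 2, 1, 1 and 1, without striatum sham replicates 2, 1, 1 and 0 and without striatum 8 h replicates 1, 2, 1 and 3. At 24 h the same omissions gave 51, 39, 26 and 139, then 77, 348, 57 and 71, 43, 134, 53 and 68 and 87, 80, 148 and 73, and the 10 named genes lost 3, 4, 5 and 0, then 1, 0, 3 and 2, 4, 1, 3 and 2 and 1, 2, 1 and 2 calls, with Otub2, Sec14l2, Smarcc1 and Josd2 passing without each array.

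Overlaps of calls were set against those of independent calls, although the tissues may share mice, which would leave their calls dependent. Of the 11813 probes tested in both tissues, 9, 90 and 231 were called higher in both at 2, 8 and 24 h, against 0.0517, 6.22 and 63.5 from independent calls. Called lower in both were 2, 71 and 175, against 0.0223, 6.17 and 60.5, and 0, 0 and 8 were called in opposite directions.

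The sham arrays showed how the blocks of tissue differed before injury. Among the named genes higher in the striatal block were genes of hypothalamus, thalamus and dopamine neurons, which no list covered. The dopamine transporter Slc6a3 was at least 12.6-fold higher (adjusted p = 2.2e-17), the hypothalamic neuropeptide genes Pmch and Hcrt were higher by 3.84 ± 0.73 and 3.81 ± 0.45 (adjusted p = 0.00029 and 4.7e-07), and the thalamic factor Gbx2 by 3.69 ± 0.39 (adjusted p = 8.8e-08). Without cortex replicate 3 Pmch was higher by 3.09. Genes of cortical projection neurons were lower in it, Fezf2 at -2.71 ± 0.32 and Tbr1 at -2.44 ± 0.40 (adjusted p = 5.5e-07 and 4.9e-05), beside Ntn5 at -2.94 ± 0.29, the myosin gene Myl4 at -2.65 ± 0.38 and Dkkl1, at least 3.29-fold lower. All 8 of 8 cortical excitatory neuron markers were lower (mean -1.64, fry adjusted p = 2.0e-05, camera adjusted p = 2.3e-07), with the glutamate transporter Slc17a7 at -2.08 ± 0.36. Oligodendrocyte markers were higher in 9 of 11, with Mobp at 1.32 ± 0.19 and Mal at 1.04 ± 0.16 (mean 0.82, fry adjusted p = 2.7e-05, camera adjusted p = 2.3e-07). Both lists had adjusted p = 1 with estimated correlation. None of the 9 medium spiny neuron markers passed (mean 0.24), and in the sham striatum these varied between arrays. The list mean had an SD of 0.515 there and 0.227 in the sham cortex, and Rgs9 was at 11.6, 11.5, 10.4 and 10.6 on striatum replicates 1 to 4.

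Immediate early genes were lower in the striatal block in 8 of 24, with Arc at -1.65 ± 0.44 and Junb at -1.35 ± 0.36 (camera adjusted p = 0.030, and 1 with estimated correlation), and synaptic genes were lower in 8 and higher in 2 of 23, with Stx1a at -1.94 ± 0.24 and Camk2a at -1.53 ± 0.27. Interneuron markers gave 3 on either side of 8, Calb2 higher by 2.18 ± 0.29 and Vip lower at -1.83 ± 0.26, and astrocyte markers were higher in 4 of 11, with Aqp4 at 0.95 ± 0.14 (fry adjusted p = 0.0019, camera 0.15, and 1 with estimated correlation). In all 3329 of 12939 probes differed, 1711 higher and 1618 lower in the striatal block, and 233 and 212 at least 2-fold. The tissues were on different BeadChips, so tissue and BeadChip cannot be told apart. The count was 2534, 2471, 2936 and 3155 without cortex replicates 1 to 4 in turn and 3111, 2758, 2543 and 2917 without striatum replicates 1 to 4, and all 9 named genes passed without each array.

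**Figure D3:**
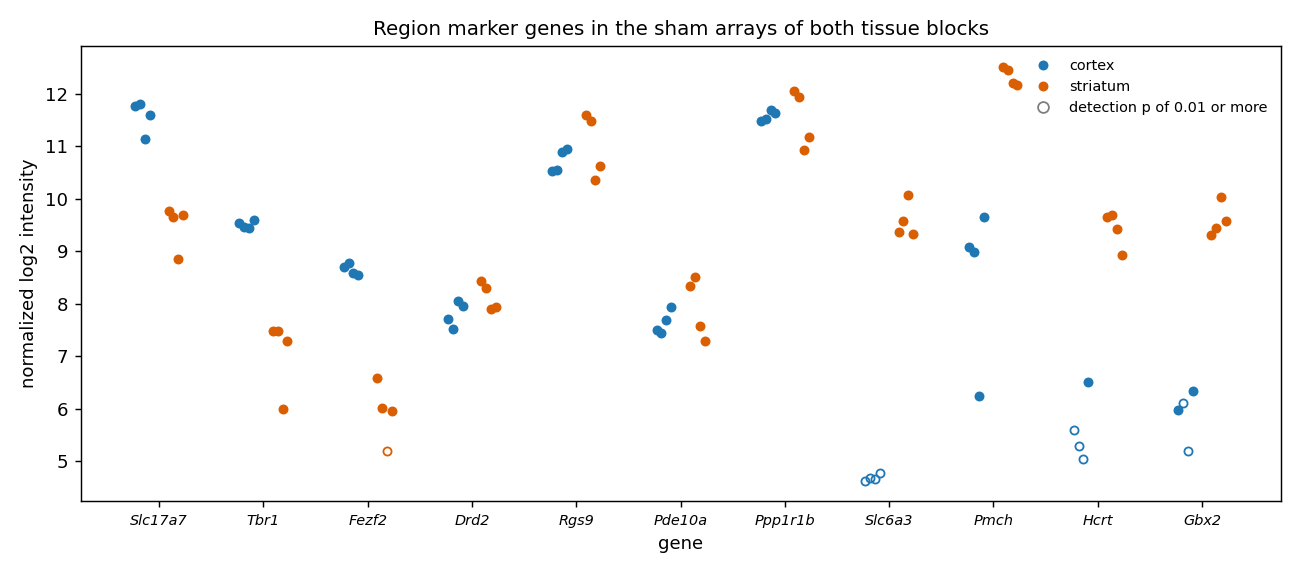
Normalized log2 intensity of 11 region marker genes on each of the 8 sham arrays by tissue, hollow symbols marking a detection p of 0.01 or more. Slc17a7 differs by -2.08 log2 between the striatal and the cortical block.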

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

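The tests chosen only after the result was seen were that of the same number in the array codes, that of tissue from other regions and that of Hba-a1 against Hbb-bt. An array stood apart where its gap to the nearest of the other 3, divided by the range of the 4, exceeded 0.829. Of 567 groups tested 32 exceeded it, 0 of 16 for array measures, 16 of 272 for list means and 16 of 279 for named genes, and chance gives about 1 in 20.

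Among sham arrays the gap was 0.924 for the nuclear factor kappa B list, lowest on striatum replicate 2, 0.832 for endothelial activation, highest on striatum replicate 4, 0.911 for the cell cycle, highest on cortex replicate 2, 0.889 for reactive astrocytes, highest on cortex replicate 3, and 0.838 for oligodendrocytes, lowest on cortex replicate 4. Among named genes in sham it was 0.852 for Cldn5, highest on cortex replicate 3, 0.955 for Timp1 and 0.924 for Depp1, both highest on striatum replicate 4, 0.835 for Ms4a6d, highest on striatum replicate 2, and 0.869 for Tbr1, lowest on striatum replicate 3. At 2 h in the cortex, replicate 2 was lowest for endothelial activation with 0.832, for monocytes with 0.902 and for Timp1 with 0.923, and replicate 1 was highest for Slc47a1 with 0.871.

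At 8 h in the cortex, replicate 2 was highest for neutrophils with 0.909 and for erythrocytes with 0.915, where its list mean was 9.50 against 7.72 on the others, and lowest for the choroid plexus with 0.875, while replicate 1 was lowest for Plin4 with 0.829 and for Ddc with 0.864. At 8 h in the striatum, replicate 1 was highest for the cell cycle with 0.915 and lowest for Sult1a1 with 0.868, replicate 3 was highest for microglia with 0.863 and lowest for the choroid plexus with 0.85, and replicate 2 was highest for pericytes with 0.893. At 24 h in the cortex, replicate 1 was highest for the interferon list with 0.829, at 9.01 against 7.35 on the others, and for Oasl2 with 0.829, and lowest for Mt3 with 0.884, replicate 2 was lowest for Plin4 with 0.848, and replicate 4 was highest for Otub2 with 0.882. At 24 h in the striatum, replicate 3 was lowest for interneurons with 0.829 and highest for Hsf4 with 0.898, and replicate 4 was lowest for Cldn5 with 0.973.

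The tissue responses differed in 2 probes at 8 h, Hr at 1.23 and Gart at -0.72, and in 110 at 24 h by the interaction test of limma. At 24 h the named genes were Gda at 1.46, Otub2 at 1.27, Sec14l2 at 1.25, Tmem114 at 1.25, Smarcc1 at 1.23, Mt3 at -1.61, Nf1 at -1.35, Hsf4 at -1.22, Josd2 at -1.16 and Tst at -1.07. By camera the lists of cholesterol synthesis and cortical excitatory neurons differed at 8 h, by 0.35 and 0.59, and that of oligodendrocytes at 24 h, by -0.40, none of them with an estimated correlation. At 2 h the count between tissues was 0, so that 100 of 100 draws of arrays into other groups had to reach it (highest other 2), and nothing was tested. At 8 and 24 h the draws could not exclude chance, with as many probes in 7 (real 2, highest other 521) and 6 (real 110, highest other 3800), the real one included. Of the 6 and 5 other draws as large, 2 and 2 followed the conditions in 1 tissue and reversed them in the other. These turn the response to injury into a difference between tissues, so their counts hold more than chance. The rest did not, and it was not tested which kind gave the highest counts.

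For the other counts only the real split of 35 gave as many probes, the smallest share possible. Other splits mixed the groups, which can lower their counts. Against sham the cortex counts at 2, 8 and 24 h were 94, 667 and 1520, and the highest others 1, 1 and 2. In the striatum they were 20, 478 and 2067, against 1, 0 and 0. For 8 h against 2 h and 24 h against 8 h they were 70 and 652 in the cortex, against 2 and 337, and 140 and 1502 in the striatum, against 1 and 14, and for sham striatum against sham cortex 3329 against 6.

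The mean of the STAT3 and acute phase list had an SD of 0.264, 0.370 and 1.12 at 2, 8 and 24 h in the cortex and 0.0719 in sham. In the striatum it varied more than in sham at 24 h, with 1.21 against 0.239, and less at 2 and 8 h, with 0.188 and 0.155. Array signal strength stays open, because its relation to the list did not pass and rested on few arrays. The deviations of the share of detected probes and of the list from their group means had r = 0.422 over 24 arrays (permutation p = 0.138, adjusted 0.164, Spearman rho 0.251, r = 0.0204 without the 2 farthest arrays, 0.536 in cortex and 0.319 in striatum). BeadChip stays open, with a mean product of deviations of 0.021 for arrays of 1 BeadChip. The extent of injury of an animal also stays open, because cortical and striatal arrays with the same number in their codes had r = 0.525 over 12 pairs and exact p = 0.244 over 13824 pairings, and the labels do not say whether these came from the same mouse.

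In the cortical block at 24 h, 3 of 9 medium spiny neuron markers fell, Rgs9, Pde10a and Drd2. Fewer neurons of every kind stay open as an explanation, since unadjusted tests differed. The spiny neuron list fell by 0.82 log2 more than the cortical excitatory list (exact p = 0.0286 over 35 splits, the smallest possible). It fell by 0.68 more than the neuron list (exact p = 0.114). Less tissue from other regions in the block could not be told apart from a change within it, because 30 probes higher by over 2 log2 units in the sham striatal block changed by -0.13 (6.16 ± 0.409 at 24 h and 6.29 ± 0.114 in sham, exact p = 0.543). Damage to such neurons was not tested.

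Hba-a1 was higher than in sham in the cortical block at 8 and 24 h and in the striatal block at 8 h. Blood left in the tissue is a candidate explanation, since its deviations went with those of the beta globin Hbb-bt with r = 0.925 over 24 arrays (permutation p = 2e-05, adjusted 6e-05, Spearman rho 0.851, r = 0.897 without the 2 farthest arrays, 0.901 in cortex and 0.954 in striatum). Hbb-bt itself passed in none of the comparisons with sham. A part in the injury response of the tissue stays open, with r = 0.344 against the STAT3 and acute phase list (permutation p = 0.164, Spearman rho 0.378, r = 0.124 without the 2 farthest arrays). The 3 relations were adjusted together.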

How the results depend on the processing

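Only the block by array codes was chosen after the data were seen. No named gene reversed with the authors' values, the fixed BeadChip block, no background correction, either replicate block or an array left out, and no count of list members with these or, in place of no background correction, without a filter. Single genes were not followed in the other alternatives. List calls changed. By fry the calls in the striatum at 2, 8 and 24 h went from 2, 1 and 1 to 0, 0 and 0 with the authors' values and to 1, 1 and 0 with the replicate block, and those for 24 h against 8 h from 2 to 0 with the authors' values. For cortex 8 h against 2 h they went from 0 to 1 with the authors' values and 2 with the fixed BeadChip block or the replicate block, and in the cortex at 2 and 24 h from 4 and 11 to 2 and 9, 3 and 13, and 3 and 12 in that order. In the cortex at 8 h they went from 4 to 5 with either block, and for cortex 24 h against 8 h from 5 to 6 with the fixed BeadChip block. The call lost in the striatum at 24 h was that of the cell cycle list (adjusted p = 0.071 with the replicate block and 0.058 by array codes). The block by replicate number kept the camera call with an estimated correlation (adjusted p = 0.046). Of the named genes tested, 117 of 145 still passed with the authors' values, 139 of 145 with BeadChip as a fixed block, 153 of 155 without background correction, 133 of 155 with the replicate block and 985 of 1336 over the omissions of 1 array, and the others kept their direction. In 367 and 382 of 442 and 3862 of 4624 cases counts of called list members stayed within 1.5 times. The order is authors' values, fixed BeadChip block and omissions, and cases of 0 in both raise the shares. Causes of moved counts were not tested, apart from omissions, which leave fewer arrays, and no filter, which adds dim probes to the adjustment.

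Scaling to the 75th percentile gave 1 probe for the tissue response at 8 h. BeadChip as a fixed block gave 13 in the striatum at 2 h and 1 for the response at 8 h, and as a random block 180 in the cortex at 2 h, 121 for cortex 8 h against 2 h and 258 for the response at 24 h. All 32 arrays processed together gave 65 and 973 in the striatum at 2 and 8 h, 43 for cortex 8 h against 2 h, and 348 and 2331 for striatum 8 h against 2 h and 24 h against 8 h. Array weights gave 1184, 2095 and 449 for cortex 2 h, 8 h and 8 h against 2 h, 94, 1041 and 295 for the same in the striatum, and 756 for the response at 24 h. The authors' values gave 424 for cortex 8 h, 8, 139, 776, 19 and 309 for striatum 2 h, 8 h, 24 h, 8 h against 2 h and 24 h against 8 h, and 1 and 0 for the responses at 8 and 24 h, the last with limma calling none and 1662 probes at an unadjusted p under 0.05. A detection p under 0.05 gave 1 and 70 for the responses at 8 and 24 h, and no background correction 196 at 24 h. Without a filter there were 45 for cortex 8 h against 2 h and 1, 299 and 86 for striatum 2 h, 8 h and 8 h against 2 h. The replicate block gave 5 and 69 for striatum 2 h and 8 h against 2 h and 0 and 35 for the responses at 8 and 24 h, and the block by array codes 0 at 8 h, where limma had 649 and 688 probes at an unadjusted p under 0.05.

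With 1 array left out the counts ranged from 11 to 98, 170 to 957 and 708 to 2762 in the cortex at 2, 8 and 24 h, and from 0 to 31, 124 to 568 and 951 to 2162 in the striatum. For 8 h against 2 h and 24 h against 8 h they ranged from 24 to 71 and 310 to 1489 in the cortex and from 34 to 150 and 487 to 2007 in the striatum, for the responses from 0 to 0, 0 to 3 and 26 to 348, and for the sham tissues from 2471 to 3155. Where limma called 0 probes, 979 to 1088 passed an unadjusted p under 0.05 in the striatum at 2 h, 511 to 847 for the response at 2 h and 459 to 880 at 8 h. The authors' ratios and BeadChip as a fixed block cannot give the comparison of sham tissues and were not run for it. Replicate numbers were not taken as pairs, since not every pair with the same number had r over 0.1. The mean r was 0.107 in the cortex (-0.198 to 0.404, 11 of 24 pairs over 0.1, mean -0.0353 for different numbers) and -0.00864 in the striatum (-0.271 to 0.222, 6 of 24), and 7 and 5 of 16 arrays were closest to their own number. By the numbers of the array codes it was 0.0459 in the striatum (10 of 24), and for arrays of 1 BeadChip 0.139 in the cortex (13 of 24, 10 of 16 arrays closest to their own BeadChip) and 0.034 in the striatum (8 of 24, 6 of 16), so a shared part of the deviations stays open.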

Other observations

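Pmch, a hypothalamic gene chosen after its values were seen, was detected on all striatal and sham cortical arrays and mostly lower in reperfused cortex. In cortex sham its log2 intensity was 9.0, 8.91, 6.17 and 9.59 on replicates 1 to 4, at 2 h 5.22, 4.88, 5.04 and 5.19, at 8 h 5.13, 5.18, 5.94 and 6.63, and at 24 h 4.94, 4.78, 10.1 and 5.16. No cortical array detected it at 2 h. It passed limma at none of these times. Less hypothalamic tissue at 2 or 8 h was not tested.

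Hba-a1, also chosen after its values were seen, passed in 3 of the 6 comparisons with sham. It did not pass at 2 h in the cortex, where no sham array detected it (adjusted p = 0.10 by limma, n = 4), at 2 h in the striatum at 4.14 ± 0.98 (adjusted p = 0.10) or at 24 h in the striatum at 2.01 ± 0.98 (adjusted p = 0.16).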
